A study of Homo sapiens with 26 samples.

How the data were processed

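H1 embryonic stem cells with a doxycycline-inducible dCas9-KRAB were profiled before and after differentiation to definitive endoderm. Per the labels' protocols, cells of the guide groups were selected with puromycin for 72 hours after lentiviral delivery of the guide. They received 500 ng/mL doxycycline from 48 hours before differentiation onwards. About 50000 cells went into each ATAC-seq library, which was sequenced as paired reads of 75 nt. The labels name 26 libraries in 13 groups of 2, and the lists of 8 groups were analysed. Nothing in the labels says whether replicates came from separate cultures.

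The deposited lists are peak positions in base pairs (chromosome, start and end), with no score, height, p-value or read count. Per the labels, 1 list stands for both replicates of a group. How the replicates were combined, the peak threshold and any filter are not given in the sources used here. The submitters' processing notes name Bowtie2 2.3.2, MACS2, DiffBind, Salmon 0.8.2 and DESeq2 without saying what each was used for, and the builds GRCh37 and hg19. Because the lists hold no depth, a peak missing from a list can be a weaker peak or one called at lower depth, and these were not separated. The lists of the guide groups had narrower ATAC-seq peaks than those without a guide, and 2 mitochondrial peaks each where the others had 0. Whether both kinds of list were made with the same steps is not given in the sources used here. The comparison of endoderm without a guide with scramble was used as background, and that with the FOXA2 guide as a second control, so the latter also holds any difference between the kinds of list.

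Positions were read as given and printed counting from 1. A peak counted as shared when at least 1 bp overlapped a peak of the other list. Each share was given with a 95% Wilson interval, which covers counting error alone, and with a jackknife SE that left out each of 23 chromosomes (the 22 autosomes and X) in turn. Peaks are not replicates, and no p-value was computed. Chance overlap with FOXA2 came from 100 circular shifts of the FOXA2 list within chromosomes. Peaks with and without a FOXA2 peak were compared as a difference in percentage points, and the bound share was placed among 10000 random sets of unbound peaks with the same number in each of 10 width classes. The same difference between endoderm without a guide and scramble served as background. Tests, groups and a list of other settings were fixed before the data were examined. The other settings changed the overlap, the peaks kept, the list length, the unit and the chromosomes. The split of ATAC-seq loss at bound and unbound peaks by presence in the ESC list was not fixed beforehand.

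Windows were named by a fixed rule: per comparison, the 10 windows of 500 kb with the highest and the 10 with the lowest net number of class-specific peaks, with ties decided by more FOXA2 peaks and then by name; the text prints the first of each side and summarises the rest. That rule applied because the gene annotation at hand was of another build (GRCh38.p14) than the lists. No gene was assigned to a peak, the gene lists and sequence motifs planned for the comparisons were not used here, and the FOXA2 locus itself was not examined. Window counts were set against the lowest and highest net of 100 random reassignments of the class-specific peaks to the 2 classes, a bound that windows with few peaks cannot pass. Because ties favour windows with FOXA2 peaks, medians of FOXA2 peaks were taken over all windows tied with the 10th. The set of chromosomes 17, 19 and 22 was chosen after seeing the data.

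Overlaps were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and checked against bedtools 2.31.1; figures were drawn with matplotlib 3.10.9. The comparison of bound and unbound peaks was tested on simulated data made from the 62184 scramble ATAC-seq peaks. A true difference of 20.0 percentage points was recovered as 20.6. Where loss depended on width alone, the difference was -1.41 before and 0.068 after matching on width, at percentile 57.7 of the matched sets.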

Results

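Chromatin was profiled in H1 human embryonic stem cells (ESC), an established pluripotent line, and in definitive endoderm derived from them, the germ layer that gives rise to the gut, liver and pancreas. The line carries an inducible dCas9-KRAB, a catalytically inactive Cas9 fused to a repressor domain that silences the gene a guide RNA points to (CRISPR interference). Endoderm was made without a guide, with a scramble control guide or with a guide against FOXA2, a forkhead transcription factor known as a pioneer factor because it can bind closed chromatin. The series holds 26 libraries in 13 groups of 2 replicates. Peak lists were analysed for 8 groups, which rest on 16 libraries: 4 groups of ATAC-seq (accessible chromatin), 3 of ChIP-seq for H3K27ac (a histone mark of active promoters and enhancers) and 1 of ChIP-seq for FOXA2 in endoderm without a guide. The 6 H3K27me3 libraries and the 4 RNA-seq libraries, which are of ESC and endoderm without a guide, were not analysed here. FOXA2 expression under either guide was not analysed here.

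The ATAC-seq lists held similar numbers of peaks. ESC had 59307 peaks over 46.9 Mb, endoderm without a guide 64695 over 58.3 Mb, scramble endoderm 62184 over 39.5 Mb and FOXA2 guide endoderm 61030 over 35.7 Mb. Median peak widths were 634, 750, 545 and 503 bp in the same order, and the widest peaks reached 6420 and 7117 bp in the lists without a guide against 3031 and 3025 bp in the guide lists. For H3K27ac, ESC had 23709 peaks over 12.8 Mb, scramble endoderm 28675 over 25.1 Mb and FOXA2 guide endoderm 29975 over 29.0 Mb. The FOXA2 list held 30966 peaks over 9.47 Mb, with a median width of 268 bp. Each list stands for the 2 replicates of its group, combined in a way that was not given, and carries no heights or read counts. Sequencing depth was therefore unknown, no spread between replicates could be given, and no p-value was computed. Unless stated otherwise, percentages below are given with a jackknife standard error (SE) over 23 chromosomes, which measures variation along the genome and not between cultures.

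Many accessible peaks differed between ESC and endoderm without a guide. Of the endoderm peaks, 57.2% (SE 1.82; 36982 of 64695) overlapped no ESC peak. Of the ESC peaks, 51.7% (SE 0.48; 30669 of 59307) overlapped no endoderm peak. Between the 2 control lists of endoderm, 27.2% of the peaks without a guide were absent from scramble and 22.7% the other way. Part of the stage shares can therefore be difference between lists. Endoderm-only peaks carried a FOXA2 peak in 33.9% of cases (SE 0.54), against 11.9% (SE 0.53) of the endoderm peaks shared with ESC and 2.81% (SE 0.12) of the ESC-only peaks. Peaks found in 1 stage alone were narrower, with medians of 520 bp for ESC-only and 661 bp for endoderm-only peaks against 853 and 962 bp for the shared peaks of each list.

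The regions with the largest net shift were read from windows of 500 kb in the coordinates of the deposited lists (GRCh37). The window on chromosome 11 from 5000001 to 5500000 had the highest excess of endoderm-only over ESC-only peaks, 23 against 1, and held 9 FOXA2 peaks. It was followed by chromosome 1 from 50500001 to 51000000, with 23 endoderm-only and 5 ESC-only peaks, and by chromosome 9 from 87500001 to 88000000, with 18 and 0. At the other end, chromosome 1 from 27500001 to 28000000 held 35 ESC-only and 0 endoderm-only peaks. Chromosome 20 from 61500001 to 62000000 held 36 ESC-only peaks and 1 endoderm-only peak, and chromosome 19 from 49000001 to 49500000 held 33 and 1. With all ties at the 10th place included, the 13 windows with the highest excess had a median of 9 FOXA2 peaks and the 12 lowest a median of 1.5, while the median over the 5645 windows was 5. In 100 random reassignments of the stage-specific peaks to the stages, the net number ranged from -16 to 27. The net fell below that range in 156 windows, on the ESC side. On the endoderm side 53 of the 5645 windows held enough stage-specific peaks to exceed 27 at all and 0 did, so this range says little about that side.

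H3K27ac peaks also differed between ESC and endoderm, for which the scramble list was used. No second control list of endoderm gave a background for these shares. Of the scramble endoderm peaks, 65.4% (SE 1.53; 18747 of 28675) overlapped no ESC peak, and 50.3% (SE 0.87; 11930 of 23709) of the ESC peaks overlapped no scramble peak. FOXA2 peaks lay in 25.0% (SE 0.75) of the endoderm-only H3K27ac peaks, in 9.19% (SE 0.60) of the scramble peaks shared with ESC and in 2.78% (SE 0.17) of the ESC-only peaks. Chromosome 4 from 140500001 to 141000000 gained most, with 26 endoderm-only peaks and 1 ESC-only peak and 24 FOXA2 peaks. Chromosome 18 from 19500001 to 20000000 followed with 23 and 0, tied with chromosome 1 from 226000001 to 226500000 with 25 and 2; they held 21 and 9 FOXA2 peaks. Chromosome 19 from 54000001 to 54500000 held 31 ESC-only against 5 endoderm-only peaks, and chromosome 1 from 17500001 to 18000000 held 23 against 0. With ties at the 10th place included, the 15 highest windows had a median of 11 FOXA2 peaks and the 12 lowest a median of 5.5, against 5 over all windows. Beyond the range of -15 to 23 that 100 reassignments gave lay 1 window on the endoderm side and 14 on the ESC side, where 39 and 272 windows held enough peaks to do so. None of the 10 highest or 10 lowest windows coincided with those for accessibility. The ESC culture had no guide and the endoderm culture had a guide and doxycycline, so stage and treatment differed together here.

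The stages also differed in where along the genome their peaks lay. Chromosomes 17, 19 and 22, picked after their values were seen, held 11.1% of the ESC and 6.61% of the endoderm ATAC-seq peaks without a guide. They held 11.2% of the ESC-only and 3.33% of the endoderm-only peaks. For H3K27ac they held 13.5% of the ESC and 10.8% of the scramble endoderm peaks.

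**Figure D1:**
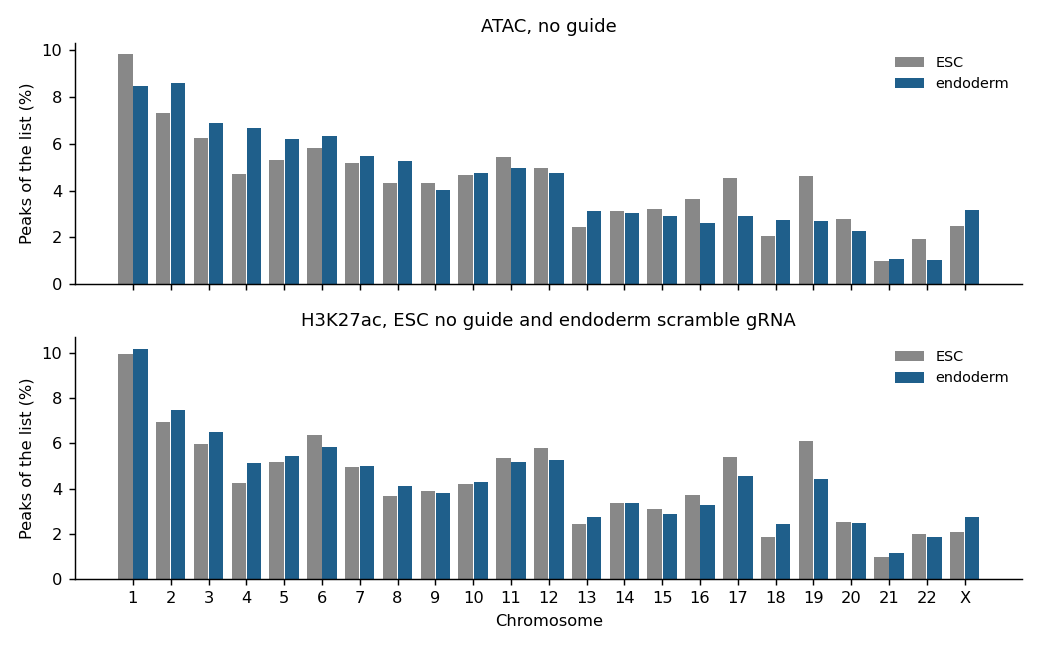
Percent of each list's peaks on each chromosome, for ESC (grey) and endoderm (blue), in ATAC-seq without a guide (top) and in H3K27ac (bottom; ESC without a guide, endoderm with the scramble guide). Chromosomes 17, 19 and 22 together held 11.1% of the ESC and 6.61% of the endoderm ATAC-seq peaks, and 13.5% and 10.8% of the H3K27ac peaks.

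Most FOXA2 peaks of endoderm had no accessible peak in ESC. Of the 30966 FOXA2 peaks, 12.7% (SE 0.32) overlapped an ESC ATAC-seq peak, 54.1% (SE 0.64) one of endoderm without a guide, 45.8% (SE 0.50) one of scramble endoderm and 32.2% (SE 0.51) one of FOXA2 guide endoderm. FOXA2 lists shifted along each chromosome gave means of 2.10%, 2.58%, 1.92% and 1.80% for the same lists. No ATAC-seq list covered 11999 of the FOXA2 peaks (38.7%, SE 0.50), and these were narrower, with a median of 235 bp against 299 bp for the others. H3K27ac covered fewer FOXA2 peaks: 3.27% in ESC, 16.9% in scramble endoderm and 16.7% in FOXA2 guide endoderm. Shifted FOXA2 lists gave means of 0.62%, 1.08% and 1.21% for these, and the FOXA2 guide list covered more base pairs than the scramble list. Both ends depended on the peaks kept. With the ATAC-seq list reduced to its widest 30966 peaks, the 54.1% of endoderm was 31.5% and the 12.7% of ESC was 7.31%; in the widest 50% of each list the ESC share was 6.70%.

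**Figure D2:**
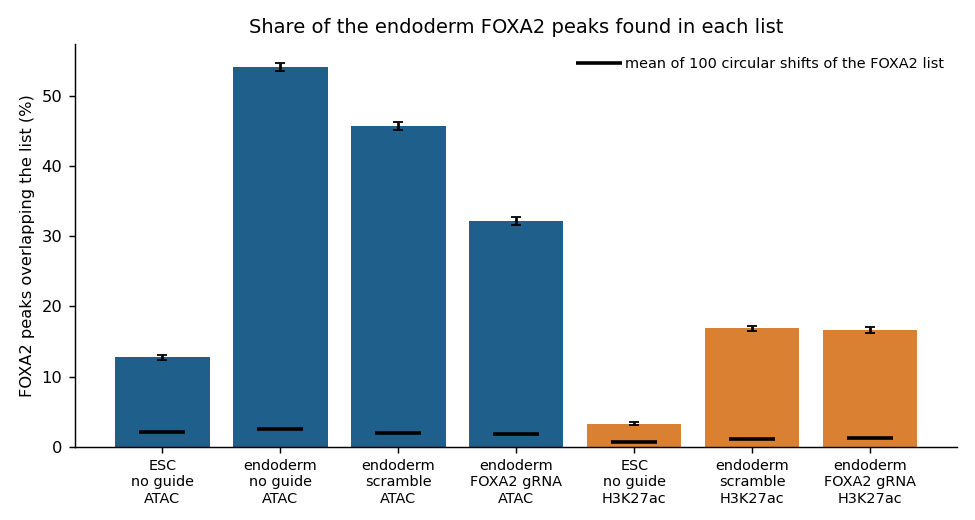
Percent of the 30966 FOXA2 peaks of endoderm without a guide that overlapped each ATAC-seq list (blue) or H3K27ac list (orange), with 95% Wilson intervals that cover counting error alone; black lines mark the mean of 100 shifted FOXA2 lists. Coverage by ATAC-seq was 12.7% in ESC, 54.1% in endoderm without a guide, 45.8% in scramble endoderm and 32.2% in FOXA2 guide endoderm. H3K27ac coverage was 16.9% in the scramble list and 16.7% in the FOXA2 guide list, against shifted means of 1.08% and 1.21%.

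The FOXA2 guide was compared with the scramble guide in endoderm. Of the scramble ATAC-seq peaks, 22.4% (SE 0.35; 13940 of 62184) had no counterpart under the FOXA2 guide, and 20.2% (SE 0.65; 12311 of 61030) of the FOXA2 guide peaks had none in scramble. The classes differed in FOXA2 occupancy: 31.0% (SE 0.90) of the scramble-only peaks, 19.5% (SE 0.68) of the scramble peaks present in both and 3.93% (SE 0.20) of the FOXA2 guide-only peaks held a FOXA2 peak. Scramble-only peaks were found in endoderm without a guide in 55.4% of cases (SE 0.79) and FOXA2 guide-only peaks in 36.6% (SE 0.63). The total exchange was no larger than that between control lists. Of the peaks without a guide, 27.2% were absent from scramble, and 22.7% of the scramble peaks were absent from the list without a guide, a comparison that also spans lists of different peak width.

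Windows of 500 kb changed by few peaks under the FOXA2 guide. The largest net loss was on chromosome 20 from 55500001 to 56000000, with 11 scramble-only and 0 FOXA2 guide-only peaks and 11 FOXA2 peaks. Of these scramble-only peaks, 3 held a FOXA2 peak. Chromosome 1 from 40000001 to 40500000 followed with 11 scramble-only peaks and 1 FOXA2 guide-only peak. The largest net gain was on chromosome 3 from 27000001 to 27500000, with 10 FOXA2 guide-only peaks and 1 scramble-only peak. With ties at the 10th place included, the 24 windows of largest loss had a median of 6.5 FOXA2 peaks. The 13 of largest gain had a median of 5, against 5 over all windows. Of 5662 windows, 4 held enough class-specific peaks to fall below the -13 of 100 reassignments and 18 to exceed their 12, and 0 did. Smaller windows could not pass this range however one-sided they were.

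Sites bound by FOXA2 lost accessibility more often than other sites mainly where ESC had no accessible peak. The split by the ESC list was not among the tests fixed beforehand. Of the scramble ATAC-seq peaks with a FOXA2 peak, 31.5% (SE 0.50; 4321 of 13721) were absent under the FOXA2 guide, against 19.8% (SE 0.39; 9619 of 48463) of those without. The difference was 11.6 percentage points (SE 0.48) and was positive on 23 of 23 chromosomes. Among scramble peaks not in the ESC list, 36.6% (SE 0.62) of the bound and 28.6% (SE 0.64) of the unbound peaks were absent, a difference of 8.04 (SE 0.49), or 13.5 (SE 0.43) at equal width. Among those also in the ESC list the shares were 14.3% (SE 0.84) and 13.9% (SE 0.54), a difference of 0.44 (SE 0.69), positive on 14 of 23 chromosomes, or 2.28 (SE 0.63) at equal width. For gained peaks the difference was reversed, as it was between control lists: 4.97% (SE 0.26) of the FOXA2 guide peaks with a FOXA2 peak were absent from scramble, against 23.1% (SE 0.85) without. That is a difference of -18.1 percentage points (SE 0.87), against -15.4 (SE 0.45) and -7.47 (SE 0.85) between the control lists in either direction. Counted by FOXA2 peak, 4725 were accessible in scramble alone and 523 under the FOXA2 guide alone. Of FOXA2 peaks accessible in scramble, 37.8% (SE 0.63) were absent under the FOXA2 guide where ESC had been closed and 17.3% (SE 0.88) where ESC had been open.

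The higher loss at bound sites did not appear between the control lists. Scramble peaks with a FOXA2 peak were absent from endoderm without a guide in 10.7% of cases (SE 0.35), against 26.1% (SE 0.41) of those without. Peaks of endoderm without a guide were absent from scramble in 21.6% (SE 0.45) and 29.1% (SE 0.83), and absent under the FOXA2 guide in 40.6% (SE 0.44) and 29.0% (SE 0.53). Narrow peaks were lost more often whether bound or not, and bound scramble peaks were the wider ones, with a median of 584 bp against 531 bp. In 10000 random sets of unbound scramble peaks matched on width in 10 classes, the loss ranged from 17.2% to 19.2%, all below the 31.5% of the bound peaks. These sets were not matched on presence in the ESC list. Absent from that list were 10564 of 13721 bound and 19617 of 48463 unbound scramble peaks, and such peaks were lost more often. As observed, the differences within the 2 ESC sets, 8.04 and 0.44, were both below the pooled 11.6, which therefore also holds this mix. The FOXA2 list came from the culture without a guide, so scramble peaks with a FOXA2 peak were picked by a signal of that culture. This favours their presence in its ATAC-seq list, so the 10.7% against 26.1% is not a neutral background. Peak width stood in for peak strength, which the lists do not give.

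**Figure D3:**
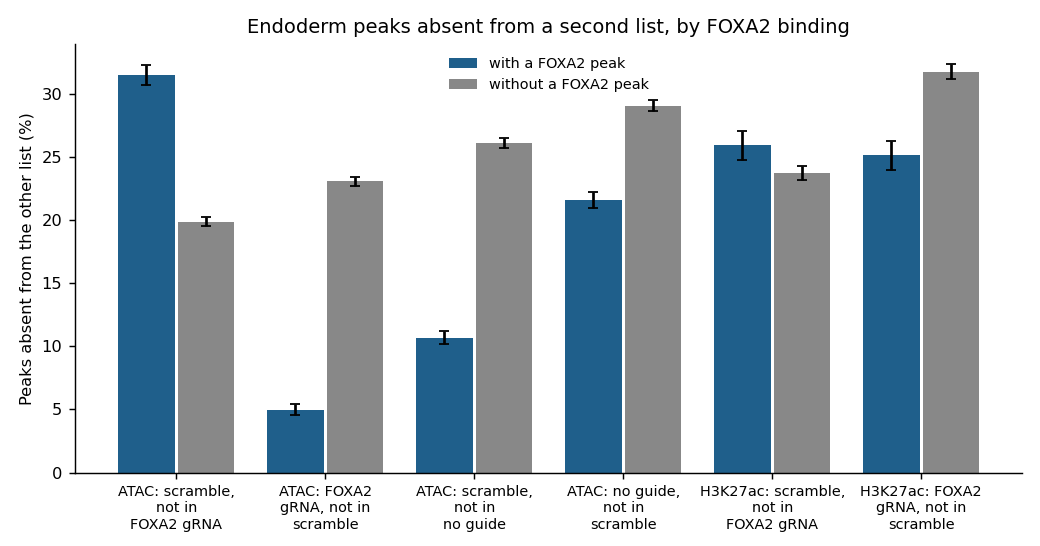
Percent of endoderm peaks absent from a second list, for peaks with (blue) and without (grey) a FOXA2 peak, with 95% Wilson intervals; each pair of bars names the list counted and the list it was compared with. Bound peaks were lost more often under the FOXA2 guide (31.5% against 19.8%), and less often between scramble and endoderm without a guide (10.7% against 26.1%), the culture that the FOXA2 list came from.

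**Figure D4:**
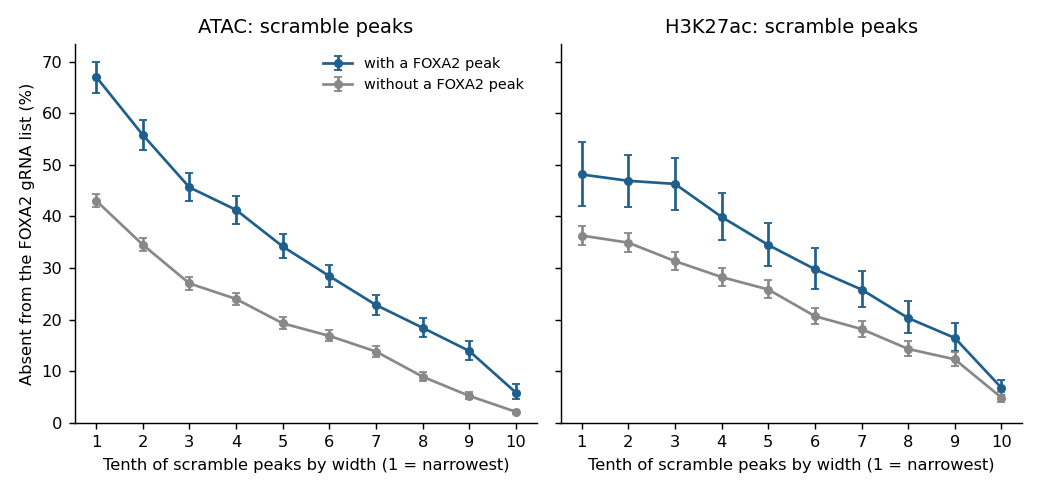
Percent of scramble ATAC-seq peaks (left) and H3K27ac peaks (right) absent under the FOXA2 guide, in 10 classes of peak width, for peaks with (blue) and without (grey) a FOXA2 peak; bars are 95% Wilson intervals. At equal width bound peaks were lost more often in both assays, by 13.3 percentage points for ATAC-seq and 7.27 for H3K27ac after weighting unbound peaks to the widths of bound peaks. Presence in the ESC list was not matched.

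Under the FOXA2 guide more H3K27ac peaks were gained than lost. Of the scramble peaks, 24.1% (SE 0.53; 6917 of 28675) were absent under the FOXA2 guide, and 30.5% (SE 0.72; 9152 of 29975) of the FOXA2 guide peaks were absent from scramble. The FOXA2 guide list was longer. With both lists cut to the same length by width, the shares were closer, at 25.9% and 29.3%. FOXA2 peaks lay in 21.0% (SE 0.77) of the scramble-only, 19.1% (SE 0.94) of the shared scramble and 14.9% (SE 0.54) of the FOXA2 guide-only H3K27ac peaks. The largest net loss was shared by 2 windows: chromosome 10 from 3500001 to 4000000, with 10 scramble-only peaks and 1 FOXA2 guide-only peak, and chromosome 1 from 27000001 to 27500000, with 11 and 2. FOXA2 peaks lay in 8 of the 10 and 3 of the 11 scramble-only peaks. The largest net gain was shared by 4 windows. Chromosome 1 from 208000001 to 208500000 held 11 FOXA2 guide-only and 2 scramble-only peaks. Chromosome 11 from 92500001 to 93000000, chromosome 5 from 141000001 to 141500000 and chromosome 14 from 105000001 to 105500000 held 9 and 0 each. With ties at the 10th place included, the 20 windows of largest loss had a median of 8.5 FOXA2 peaks and the 14 of largest gain a median of 7, against 5 over all windows. Of the windows, 60 held enough class-specific peaks to fall below the -10 of 100 reassignments and 16 to exceed their 12, and 0 did on either side; smaller windows could not. No H3K27ac list without a guide in endoderm was analysed here, so no list-to-list background could be set beside these values.

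Loss of H3K27ac differed less by FOXA2 occupancy than loss of accessibility did. Scramble H3K27ac peaks with a FOXA2 peak were absent under the FOXA2 guide in 25.9% of cases (SE 0.73; 1450 of 5598), against 23.7% (SE 0.58; 5467 of 23077) without. The difference was 2.21 percentage points (SE 0.86), positive on 16 of 23 chromosomes. Gained peaks made up 25.1% (SE 0.51) of the bound and 31.7% (SE 0.91) of the unbound FOXA2 guide peaks, a difference of -6.61 (SE 0.97) that was 0.45 at equal width. The direction of the difference turned with the definition. It was -3.35 percentage points when 50% of the shorter peak had to be shared, a rule that also decided which peaks counted as bound. Total scramble loss was 24.4% under that rule against 24.1%. In the widest 50% of each list, the FOXA2 list included, the difference was -3.35. Bound H3K27ac peaks were wider, with a median of 898 bp against 635 bp, and at equal width the difference was 7.27 percentage points. Neither the 2.21 nor the 7.27 was matched on presence in the ESC list. Outside that list bound peaks were lost less often than unbound ones, counted without matching on width.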

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

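The ATAC-seq lists of the guide groups held peaks on the mitochondrial genome, which no comparison used: 2 in scramble endoderm and 2 in FOXA2 guide endoderm, above the 0 in ESC and in endoderm without a guide. What separates these lists was not tested.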

How the results depend on the processing

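All 7 main results were recomputed under the settings fixed beforehand. Weighting by width, restricting the scramble peaks, using the list without a guide as control, binding within 500 bp and leaving out chromosomes 17, 19 and 22 were chosen after seeing the data. Splitting the ATAC-seq loss by presence in the ESC list was not planned either, and its values are not counted below. Among 51 alternative values, 19 were counted as within the 95% interval of the reported value. Another 30 moved outside it with the same sign (17 higher, 13 lower) and 2 reversed. For endoderm-only H3K27ac this count took the interval width from the 23709 ESC peaks. Its value with 50% of the shorter peak shared, 65.94%, is among the 19. It lies just above 65.93%, the upper limit for the 28675 scramble peaks. The endoderm-only ATAC-seq share of 57.2% was 55.9% with peaks within 500 bp counted as shared, 52.7% in the widest 50% of each list, 56.0% at equal list length, 58.1% by base pairs and 59.2% without chromosomes 17, 19 and 22. In the first 4 of these settings, in the same order, scramble ATAC-seq loss (22.4%) was 21.4%, 25.4%, 21.9% and 29.2%, and scramble H3K27ac loss (24.1%) was 20.4%, 29.2%, 25.9% and 26.3%. Endoderm-only H3K27ac (65.4%) was 59.9%, 70.4%, 64.4% and 76.1%, and 67.3% without those chromosomes. FOXA2 peaks in the endoderm list (54.1%) were 56.9%, 45.1%, 31.5% and 58.9%. The ATAC-seq loss difference of 11.6 percentage points was 10.5 within 500 bp, 16.1 in the widest 50%, 13.5 by base pairs, 13.3 weighted by width and 16.1 among scramble peaks also found without a guide. The H3K27ac loss difference of 2.21 was -3.35 with 50% of the shorter peak shared and -3.35 in the widest 50%. It was 0.92 at equal length, 0.22 by base pairs and 7.27 weighted by width. For both loss differences, the 50% and 500 bp rules fixed beforehand also decided which peaks counted as FOXA2-bound. The widest 50% also cut the FOXA2 list. The equal-length setting removes peaks by construction; for the other changes the cause was not tested. No paired analysis was possible because 1 list stands for the 2 replicates of each group. Leaving out each replicate was not run for the same reason. The gene and motif alternatives were not run. Depth is unknown, which limits every statement that a peak was absent.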

Other observations

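The tests below were chosen after the results they bear on were seen; random sets matched on width had been fixed earlier, while the width-weighted differences had not. Loss of accessibility and of H3K27ac went together at single sites. Among scramble ATAC-seq peaks with a scramble H3K27ac peak within 500 bp, FOXA2-bound peaks that were absent under the FOXA2 guide had no H3K27ac peak there in 49.6% of cases (427 of 861), against 12.6% (423 of 3369) where the ATAC-seq peak was kept. Unbound peaks gave 33.7% (449 of 1334) and 8.29% (978 of 11798). The ATAC-seq peaks that were kept were wider, with medians of 775 against 492 bp for bound and 879 against 419 bp for unbound peaks, and these shares were not matched on width.

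Peaks gained under the FOXA2 guide differed between the assays. FOXA2 guide-only ATAC-seq peaks were in the ESC list in 23.2% of cases (SE 1.06), against 32.0% (SE 1.94) of scramble-only peaks. FOXA2 guide-only H3K27ac peaks were in the ESC H3K27ac list in 16.7% (SE 1.22), against 9.04% (SE 0.57) of scramble-only peaks. Of the FOXA2 guide-only H3K27ac peaks, 68.9% (SE 0.72) lay over an ATAC-seq peak of endoderm without a guide, against 46.0% (SE 1.09) of the scramble-only peaks. ATAC-seq peaks open since ESC were lost less often under the FOXA2 guide than those that were not, 14.0% (SE 0.54) against 31.4% (SE 0.59), and were also gained less often, 9.30% (SE 0.30) against 31.2% (SE 0.46). In scramble they were wider, with medians of 704 bp bound and 656 bp unbound against 554 and 424 bp, and these shares were not matched on width.

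FOXA2-bound ATAC-seq peaks were lost more often under the FOXA2 guide than unbound ones. As far as width measures strength, bound scramble peaks were not the weaker ones, with a median of 584 bp against 531 bp for unbound peaks. Wide peaks were lost less often, so matching on width tends to raise the difference and is no separate test of weaker peaks. At equal width the difference was 13.3 percentage points (SE 0.43). A shallower FOXA2 guide list was not tested, because the lists hold no depth. Stem cells left in the FOXA2 guide culture could dilute endoderm peaks. If they did so alike whether bound or not, no difference would remain among peaks absent from the ESC list. There the difference was 8.04 (SE 0.49) as observed and 13.5 (SE 0.43) at equal width. Among peaks open in ESC it was 0.44 (SE 0.69) as observed and 2.28 (SE 0.63) at equal width. The size of both, and any difference at ESC-open sites, depended on the weighting. Equal dilution was assumed and absence from a list is a threshold call, so such cells are not excluded. From the narrowest to the widest of 5 width groups of FOXA2 peaks, the observed loss was 28.9%, 33.5%, 34.9%, 31.9% and 28.2%, a difference of -0.75 (SE 1.67), and a difference of 10.5 percentage points (SE 1.78) between the widest and narrowest appeared after weighting to equal ATAC-seq width (48 peaks in the smallest class); that accessibility may depend on FOXA2 is a hypothesis that rests here on this weighting and on the differences at equal width. A difference between the 2 cultures unrelated to the guide stays open, because each group has 1 list.

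The small H3K27ac difference at FOXA2 sites may come from peak width or from presence in the ESC list, which were not separated. Wide H3K27ac peaks were rarely lost, FOXA2-bound ones were wider, and at equal width the difference was 7.27 percentage points (SE 0.75). Presence in the ESC list was not matched. Scramble H3K27ac peaks in that list were lost in 6.30% of cases (SE 0.27), against 33.6% (SE 0.56) of the others. The others also held a FOXA2 peak more often, 25.0% against 9.19%, so this mix also enters the 2.21 and may account for part or all of the 7.27. Of the 4686 bound peaks outside the ESC list, at most 1450 were lost, the number of all lost bound peaks. That share is below the 33.6% of all peaks outside the list. Bound peaks there were thus lost less often than unbound ones, counted without matching on width. Whether the longer FOXA2 guide list hid a loss stays open: at the same length the difference was 0.92, but 7.0% of the 1300 narrow peaks removed held a FOXA2 peak against 18.1% of the list, which lowers the difference by itself. Gained H3K27ac at equal width differed by 0.45 percentage points, at percentile 81.6 of the matched sets. With a FOXA2 peak counted within 500 bp, it differed by 0.95, at percentile 98.8. Whether the guide or depth set the width of H3K27ac peaks was not tested.

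Endoderm peaks were scarcer on chromosomes 17, 19 and 22, which are rich in genes. These chromosomes held 11.1% of the ESC ATAC-seq peaks and 6.61% of those of endoderm without a guide, and 11.2% of ESC-only against 3.33% of endoderm-only peaks. A bias of the ATAC-seq libraries as the whole cause was not borne out, since the H3K27ac share was also lower in endoderm, by -2.70 percentage points (SE 0.29), nor were weak ESC peaks, since the widest 50% of the ATAC-seq lists differed by -5.33 (SE 0.25). FOXA2 sites did not account for it either: endoderm-only peaks without FOXA2 were at 3.37%, -7.81 (SE 0.21) from the ESC-only peaks. The SEs in this paragraph cover counting error alone, with peaks taken as independent, and not variation along the genome. The chromosomes were also picked after their values were seen. A GC bias common to both assays was not tested, and a stage difference in where new sites open stays possible.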
